A study of Mus musculus with 8 samples.

How the data were processed

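Labelled RNA from pancreatic beta cell samples of C57BL/6 mice was measured on Agilent mouse arrays, with 4 biological replicates on the control diet and 4 on the high-fat diet. Each sample had 1 array and 1 dye. Per the file headers, the scanner files were made by Feature Extraction 11.5.1.1 and hold 1 line per spot with its signal in intensity units. The deposited value table holds log2 values for the same arrays, and the authors name limma for its processing without a version or parameters, so the steps behind it are not known in full. The labels call the samples biological replicates and do not pair them.

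The processed signal of each spot, in intensity units as deposited, was put on the log2 scale and the array's 75th percentile was subtracted. Control spots and spots marked as outliers by the scanner software were left out, and the spots of a probe were averaged. Between 125 and 228 outlier spots per array were left out. Probes well above background on at least 4 of 8 arrays were kept, 26076 in all, and the probe with the highest mean stood for a gene with several probes, which gave 19981 genes. The arrays had 43020 non-control spots each, and the median SE of a log2 difference was 0.17. Probe positions are those of the scanner files, on mm9.

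Differences between diets were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) and p-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. Where p-values are called adjusted over the list alone, the adjustment covers only the members of that list. Gene lists, 27 of pathways and 12 of cell types, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, with fry and by exact permutation of list means. Camera leaves out the 130 genes with a missing value. The lists were written by hand, without a pathway or ontology database, and were not checked against one, so each list result rests on that choice of members. They were written before the data were examined, as was the rule for naming genes: the 12 higher and 12 lower genes with the smallest unadjusted p, up to 4 genes per list, and a fixed set of hormone and marker genes. Some genes that this rule names are not reported here. Lists needed at least 5 measured members. Similarity of arrays was the mean Pearson correlation within groups minus that between groups, with an exact permutation test over the 35 splits. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

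The procedure was tested on simulated data. Independent normal noise with each gene's residual SD was drawn around its mean level, and set shifts were added to some genes. The simulated arrays had no slide effect and no correlation between genes. The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the deposited value table, no filter or a stricter filter on dim probes, the mean of a gene's probes, a trended and robust eBayes, array weights, the slide or the replicate number as a block, each slide alone, and leaving out each sample in turn. A further one, normexp without spots whose local background exceeds 4 times the median of their array, was added after the planned normexp had been seen. On high-fat replicate 2 a bright smear over 7 spots, with a local background of up to 261989 intensity units, moves the normexp fit of the whole array. Leaving out such spots was decided on after the planned version had turned the sign of 22 named genes and 6 lists, so the planned version is reported in full. The imprinted gene list was written after Mest and Nnat had been seen to be lower.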

Results

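Gene expression was profiled in samples that the labels describe as pancreatic beta cells of C57BL/6 mice, taken from animals on a chow control diet or on a high-fat diet. Each diet had 4 biological replicates, and each replicate was hybridised to its own Agilent array with Cy3 as the only dye. The 8 arrays carried 43020 non-control spots each, of which between 63.6% and 68.6% were well above background, and no spot was saturated. The 75th percentile of the signal ranged from 335.8 to 715.4 intensity units, with both extremes in control samples, and the median SE of a gene's log2 difference was 0.17. The arrays lay on 2 slides, each scanned in its own session, and each slide held 2 arrays of each diet. On both slides the control arrays occupied positions 1 and 3 and the high-fat arrays positions 2 and 4, so array position and diet cannot be told apart. How the cells were isolated is not given in the sources used here. Probes for hormones of the other islet endocrine cells and for acinar enzymes were well above background on all 8 arrays. Log2 levels in the control samples, relative to each array's 75th percentile, were 7.92 ± 0.20 for glucagon (Gcg), 7.23 ± 0.096 for somatostatin (Sst) and 8.52 ± 0.55 for the acinar elastase Cela3b (SD, n = 4).

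The question put to these arrays is how expression in the beta cell samples differed between the high-fat and the control diet. The lists for which the samples of the diets did not overlap were those of alpha cells and of delta and PP cells, which were lower, and that of the unfolded protein response, which was higher. With no diet difference each of the 39 lists has a probability of 2.86% of such a gap, so chance is not excluded for these lists. Where signs are said below to turn with normexp background correction, a background smear over 7 spots of 1 array has moved that fit. Without the smeared spots, a setting added after the planned one was seen, no named gene and no called list turned sign. The mean log2 difference was -0.53 for the alpha cell list (11 members), -0.30 for the delta and PP cell list and 0.36 for the list of the unfolded protein response. Over all 8 arrays the main beta cell hormones stood close to 0: the log2 difference, high-fat minus control, was 0.028 ± 0.19 for Ins1, 0.047 ± 0.17 for Ins2 and 0.036 ± 0.20 for amylin (Iapp, SE), and each of these signs turns with quantile normalization. These means average opposite differences on the slides. Ins1, Ins2 and Iapp stood at 0.38, 0.44 and 0.39 on slide 1 and at -0.32, -0.34 and -0.32 on slide 2. For single genes, no difference passed the test. Of 19981 genes, limma called 0 higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.125. At an unadjusted p under 0.05 there were 1171 genes, 517 higher and 654 lower, where chance alone gives about 999. Of the 35 splits of the 8 arrays into 4 and 4, 12 gave at least as many genes at that p, the split by diet included, and the split by slide gave 3818. The 4 samples of one diet did not overlap with the 4 of the other for 3.45% of the genes, against 2.86% by chance. With the median in place of the 75th percentile for scaling, 66.6% of the genes at an unadjusted p under 0.05 were higher, against 44.2% here, so the balance of directions across single genes rests on the scaling. With the slide as a block the count past the threshold was 0, and it was 0 within slide 1 and 0 within slide 2.

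Arrays of the same diet were not shown to be more alike than arrays of different diets. Arrays of the same diet correlated with each other at a mean Pearson r of 0.977 over the genes tested, and arrays of different diets at 0.976. The difference of 0.00099 had a one-sided exact permutation p of 0.314 over the 35 splits of the arrays into 4 and 4. The same statistic for the 2 slides was 0.00366, with an exact p of 0.0857, where the smallest p this design allows is 0.0286. The first principal component held 31.0% of the variance and the next 23.1%, and the diets overlapped on both. The slides did not overlap on the first, with slide 1 between -51.5 and 8.19 and slide 2 between 9.41 and 43.3. On the third, with 14.3%, they did not overlap, with control samples between 11.7 and 35.7 and high-fat samples between -33.2 and 1.26.

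Among named genes with higher signal after the high-fat diet, 12 were taken by the smallest unadjusted p, 11 of which are given here, and none passed the adjusted threshold. The log2 difference was 2.88 ± 0.55 for Reg3a, a secreted C-type lectin of the regenerating family (well above background on 3 control and 4 high-fat arrays). It was 1.39 ± 0.24 for Ankrd34b, 1.26 ± 0.22 for Gsto2, a glutathione transferase of the omega class, and 1.07 ± 0.19 for Inhbb, which encodes the beta B subunit of inhibin and activin. The dystrophin-associated delta sarcoglycan Sgcd differed by 1.06 ± 0.16, the palmitoyltransferase gene Zdhhc22 by 1.02 ± 0.18 and the mitochondrial malic enzyme Me3 by 0.89 ± 0.17. Smaller differences were 0.67 ± 0.10 for Tafa1, 0.67 ± 0.13 for Gpihbp1, which carries lipoprotein lipase in capillaries, 0.66 ± 0.12 for the ADP receptor P2ry1 and 0.62 ± 0.11 for the collagen Col16a1. Adjusted p ranged from 0.298 to 0.367 over these 11 genes. For each of them every high-fat array lay above every control array, so the sign had to be the same on both slides. Genes taken by the smallest p in these arrays tend to show such a gap, so it is no separate support. The probe of Sgcd lies at chromosome 11, 46784687 to 46784746 of mm9, with levels of -1.76 ± 0.19 in control and -0.70 ± 0.25 in high-fat samples (SD, n = 4), and that of Reg3a lies at chromosome 6, 78333635 to 78333694.

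The 12 genes with lower signal, 11 of which are given here, were led by Gfra3, a receptor subunit for the neurotrophic factor artemin. Its log2 difference was -1.17 ± 0.11, a 2.24-fold lower signal, with levels of 0.29 ± 0.050 in control and -0.88 ± 0.18 in high-fat samples (SD, n = 4). Its probe lies at chromosome 18, 34849560 to 34849619 of mm9, the difference was -1.19 on slide 1 and -1.14 on slide 2, and the limma adjusted p was 0.125. Of the 22 alternative settings, 2 took this gene past the threshold, the deposited value table (adjusted p = 0.0395) and a trended, robust eBayes (adjusted p = 0.0408), within a range from 0.0395 to 0.691. Next came Dennd2a at -0.95 ± 0.11 (probe at chromosome 6, 39412503 to 39412562, adjusted p = 0.156) and Mbl2, a mannose-binding lectin, at -1.25 ± 0.16, which was well above background on 4 control but only 2 high-fat arrays. The imprinted gene Mest differed by -0.84 ± 0.13, with 3 of its 3 probes lower. The potassium channel Kcnh8 differed by -0.85 ± 0.14, the elongation factor Eef1a2 by -1.04 ± 0.17, the actin-binding gene Actn3 by -1.01 ± 0.15 and the uroplakin Upk3a by -0.92 ± 0.15. Insyn2a differed by -1.16 ± 0.19 (well above background on 4 control and 3 high-fat arrays), Fam163a by -0.74 ± 0.11 and Klhl13 by -0.72 ± 0.11. With normexp background correction the sign turns for Mbl2, Actn3, Fam163a, Insyn2a, Kcnh8 and Eef1a2. Adjusted p lay between 0.125 and 0.298, and every high-fat array lay below every control array for each of the 11. That gap is favoured by the choice by smallest p and fixes the same sign on both slides, so neither is separate support.

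**Figure D1:**
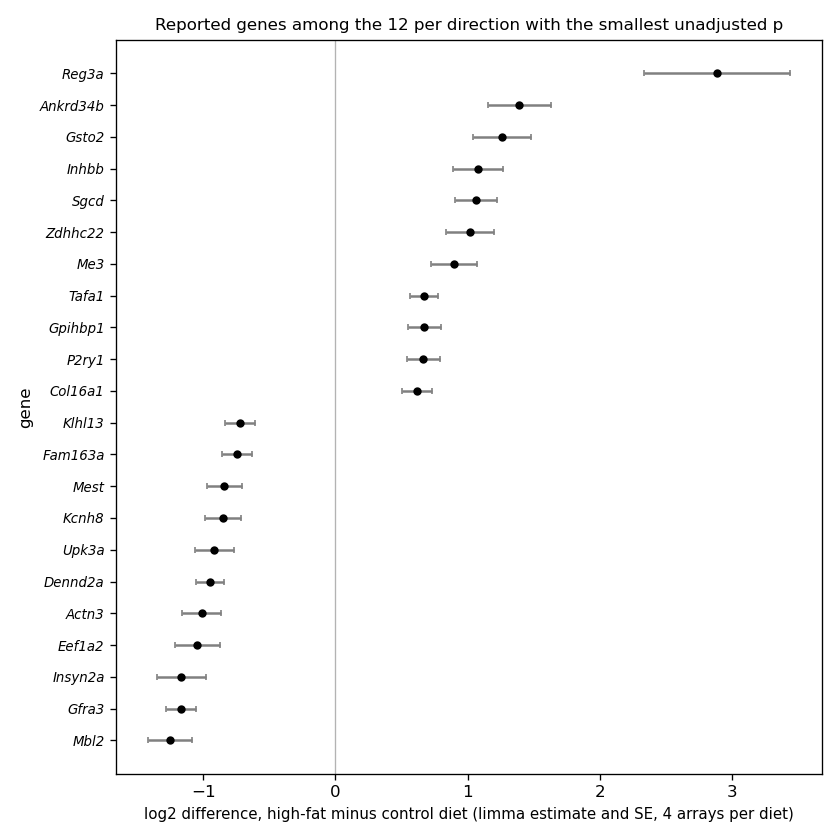
Log2 difference between diets (x axis, high-fat minus control, log2 units) for 11 higher and 11 lower genes among those with the smallest unadjusted p (y axis, gene symbols). Points are limma estimates from 4 arrays per diet and bars their SE; Reg3a at 2.88 lies farthest to the right and Mbl2 at -1.25 farthest to the left. Reg3a and Mbl2 were not well above background on every array. No gene passed the adjusted threshold, and Mbl2, Actn3, Fam163a, Insyn2a, Kcnh8 and Eef1a2 turn sign with normexp background correction.

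Genes of alpha cells were lower as a list. Of 11 measured members 9 had a log2 difference below 0, 5 were lower at an unadjusted p under 0.05, 5 were lower adjusted over the list alone and 0 passed over all genes tested. The list fell by 0.53 on average (camera adjusted p = 1.12e-06; adjusted p = 0.184 with an estimated correlation), and its mean was -0.31 with normexp background correction and -0.27 in the deposited value table. Among them are the homeobox genes Irx1 at -1.10 ± 0.22 and Irx2 at -0.78 ± 0.23. The hormone of these cells moved little, with a difference of -0.16 ± 0.16 for Gcg, which was 0.10 on slide 1 and -0.43 on slide 2, and from -0.28 without high-fat replicate 1 to -0.087 without control replicate 3. The list difference was -0.41 on slide 1 and -0.66 on slide 2, and with the slide as a block its camera adjusted p was 4.55e-06.

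Delta and PP cell genes fell by 0.30 on average over 8 measured members (camera adjusted p = 2.38e-04; adjusted p = 0.184 with an estimated correlation). Of these, 4 were lower adjusted over the list alone and 0 over all genes. They were Hhex, the homeobox factor of delta cells, at -0.60 ± 0.10, the retinol carrier Rbp4 at -0.44 ± 0.090, somatostatin (Sst) at -0.39 ± 0.097 and the ghrelin receptor Ghsr at -1.01 ± 0.30, whose sign turns with normexp background correction. Pancreatic polypeptide (Ppy) stood at -0.034 ± 0.24. The list difference was -0.38 on slide 1 and -0.23 on slide 2, with an adjusted p of 2.62e-04 with the slide as a block and 0.153 on slide 2 alone. The rotation test fry, which asks whether the genes of a list move one way and does not set them against other genes, called the alpha and the delta and PP lists and no other (adjusted p = 0.0469 for both).

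Genes of the unfolded protein response and chaperones of the endoplasmic reticulum rose as a list. Of 32 measured members 31 lay above 0, 12 were higher at an unadjusted p under 0.05, 0 were higher adjusted over the list alone and 0 over all genes. The mean difference was 0.36, a 1.29-fold higher signal (camera adjusted p = 1.54e-13; adjusted p = 0.308 with an estimated correlation). Examples are 0.96 ± 0.22 for Derl3 and 0.59 ± 0.15 for the cochaperone Dnajb11. The signal peptidase subunit Sec11c stood at 0.64 ± 0.17 and the chaperone Hsp90b1, also called GRP94, at 0.39 ± 0.11, the latter turning sign with normexp background correction. The list difference was 0.30 on slide 1 and 0.44 on slide 2, and with the slide as a block the adjusted p was 4.51e-12. With normexp background correction the mean was 0.017 and the list was not called (adjusted p = 0.236), and without the smeared spots it was 0.33 and called (adjusted p = 2.45e-13). Ddit3, the stress-induced factor CHOP, differed by -0.12 ± 0.17 (from -0.24 without control replicate 4 to -0.044 without control replicate 2), and the list of the integrated stress response did not pass (mean 0.12, camera adjusted p = 0.104).

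Oxidative phosphorylation, ribosomal protein and proteasome genes were higher by smaller amounts, a direction that turns for all 3 lists with normexp background correction, which moves the median of all genes by 0.13. Without the smeared spots that median was 0.029 and the list means were 0.14, 0.14 and 0.050, with the first 2 called (adjusted p = 4.14e-07 and 3.82e-06) and the proteasome not (0.296). Of 61 oxidative phosphorylation genes 59 lay above 0 and 2 were higher at an unadjusted p under 0.05, with a mean of 0.15 (camera adjusted p = 3.02e-10; adjusted p = 0.608 with an estimated correlation). Ndufa1 of complex I differed by 0.38 ± 0.14 and Uqcrq of complex III by 0.32 ± 0.13, and both turn sign with normexp background correction. All 56 ribosomal protein genes lay above 0 and 0 of them at an unadjusted p under 0.05, with a mean of 0.15 (camera adjusted p = 4.73e-07; adjusted p = 0.681 with an estimated correlation). The proteasome list had a mean of 0.075 over 31 members (camera adjusted p = 0.0102; adjusted p = 0.681 with an estimated correlation), with 0 members at an unadjusted p under 0.05. Slide 1 gave 0.21, 0.35 and 0.037 for these 3 lists and slide 2 gave 0.10, -0.046 and 0.12, so the ribosomal difference was absent from slide 2. Without high-fat replicate 2 the means came to 0.093, 0.099 and 0.031, and the proteasome list was no longer called, as without control replicate 3 (0.054) or 4 (0.058), while it was 0.12 without control replicate 2. The ribosomal mean was 0.064 without control replicate 1 and 0.26 without control replicate 3. After quantile normalization the camera adjusted p was 0.0534, 0.235 and 0.739 for the 3 lists, and none was called, and in the deposited value table the proteasome mean was -0.0024.

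Lipid metabolism genes went both ways. The list of fatty acid oxidation and PPAR targets rose by a mean of 0.14 (camera adjusted p = 0.00488; adjusted p = 0.608 with an estimated correlation), with 5 of 35 members higher and 0 lower at an unadjusted p under 0.05. Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, differed by 0.58 ± 0.14, the thiolase Acaa2 by 0.44 ± 0.11, the acyl-CoA dehydrogenase Acadvl by 0.33 ± 0.12 and the uncoupling protein Ucp2 by 0.32 ± 0.11. On slide 2 the list mean was 0.011 (adjusted p = 0.332) against 0.26 on slide 1. The call was also lost with normexp background correction (0.064, adjusted p = 0.389) and without high-fat replicate 2 (0.097, 0.0538), and the mean was 0.077 without control replicate 1. The list of cholesterol synthesis and uptake fell by 0.14 on average over 25 members, 4 of them lower at an unadjusted p under 0.05 (camera adjusted p = 0.0116; adjusted p = 0.681 with an estimated correlation). The sterol carrier Stard4 differed by -0.52 ± 0.15, with list means of -0.12 on slide 1 and -0.17 on slide 2, where the list was not called (adjusted p = 0.218). It was not called without control replicate 2 (-0.078, adjusted p = 0.472) or high-fat replicate 4 (-0.076, 0.132). The fatty acid synthesis list did not pass (mean -0.017, camera adjusted p = 0.710), and the stearoyl-CoA desaturase Scd1 differed by -0.59 ± 0.23 (-0.37 without control replicate 3). Acadvl and Scd1 turn sign with normexp background correction.

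Genes of beta cell identity did not pass as a list: of 34 measured members, 17 lay above and 17 below 0, with 1 higher and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.153). The glucose transporter Slc2a2 differed by -0.47 ± 0.19 (-0.30 without high-fat replicate 4, -0.22 on slide 1 and -0.72 on slide 2). The beta cell transcription factors Mafa and Pdx1 differed by -0.19 ± 0.15 (-0.097 without high-fat replicate 2) and -0.18 ± 0.13 (-0.12 without control replicate 4), and the maturity marker Ucn3 by 0.037 ± 0.17. The glucose-6-phosphatase G6pc2 differed by 0.33 ± 0.11, the imprinted gene Nnat by -1.18 ± 0.29 and the channel Trpm5 by -0.63 ± 0.24; Ucn3 and G6pc2 turn sign with normexp background correction. In the list of dedifferentiation and immature beta cell markers, 2 of 14 genes were higher and 2 lower adjusted over the list alone, and the list as such did not shift one way (camera adjusted p = 0.749). Aldh1a3, a retinaldehyde dehydrogenase used as a marker of failing beta cells, was 4.62-fold higher adjusted over the list alone, at a log2 difference of 2.21 ± 0.45 with 1.72 on slide 1 and 2.69 on slide 2, and its adjusted p over all genes was 0.392. Serpina7 stood at 1.90 ± 0.59 (0.91 on slide 1 and 2.90 on slide 2), and the endocrine progenitor factor Neurog3 at -0.73 ± 0.16.

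Genes for ion channels of beta cell excitability fell by 0.17 on average (camera adjusted p = 0.00388; adjusted p = 0.608 with an estimated correlation), with 1 of 29 higher, 5 lower at an unadjusted p under 0.05 and 3 lower adjusted over the list alone. The inositol trisphosphate receptor Itpr1 differed by -0.72 ± 0.14, and the potassium channels Kcnk3 and Kcnn2 by -0.55 ± 0.12 and -0.58 ± 0.14. The calcium pump Atp2a3 differed by 0.29 ± 0.10. With normexp background correction Kcnn2 and Atp2a3 turn sign and the list mean was -0.065, against -0.073 in the deposited value table and -0.099 with median scaling. The list mean was -0.13 on slide 1 and -0.22 on slide 2.

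Cell cycle genes rose over all 8 arrays but went opposite ways on the slides. The list mean was 0.33 over 33 members, 2 of them higher at an unadjusted p under 0.05 (camera adjusted p = 2.75e-04; adjusted p = 0.681 with an estimated correlation). The list mean was -0.26 on slide 1, where camera called the list lower (adjusted p = 0.00200), and 0.92 on slide 2. A call within 1 slide rests on 2 arrays per diet and the preset correlation, against an estimated 0.76 for this list. It is weak evidence of a diet effect. Without high-fat replicate 4 it came to 0.041 and the list was no longer called, against 0.62 without high-fat replicate 1. The ribonucleotide reductase subunit Rrm2 differed by 0.77 ± 0.23, the kinase Cdk1 by 1.16 ± 0.48, and Mki67, the gene of the proliferation antigen Ki-67, by 0.72 ± 0.54, with -0.46 on slide 1 and 1.90 on slide 2. Without high-fat replicate 4 the difference was 0.74 for Cdk1 and 0.29 for Mki67, and without high-fat replicate 1 it was 1.18 for Mki67; Cdk1 stood at 0.52 on slide 1 and 1.81 on slide 2.

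Camera at the preset correlation also called lists of markers of other cells in the samples. The Reg family, secreted proteins made by acinar and regenerating islet cells, was higher by a mean of 1.34 over 6 members, a 2.53-fold difference (camera adjusted p = 2.24e-05; adjusted p = 0.503 with an estimated correlation). Of these, 2 genes were higher adjusted over the list alone, Reg3a at 2.88 ± 0.55 and Reg2 at 1.82 ± 0.59, with Reg3b at 1.00 ± 0.50 (0.55 without high-fat replicate 2, 1.63 on slide 1 and 0.37 on slide 2). The Reg mean was 0.79 with normexp background correction and 0.84 in the deposited value table. The difference was 2.33 on slide 1 and 0.35 on slide 2, where it was not called (adjusted p = 0.102). Acinar genes, whose sign turns with normexp background correction, had a mean of 0.15 over 28 members, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0487; adjusted p = 0.738 with an estimated correlation). They were higher on slide 1 by 0.78 but stood at -0.47 on slide 2, where camera called them lower (adjusted p = 1.36e-05). That call rests on 2 arrays per diet and the preset correlation, against an estimated 0.90 for this list, so it is weak evidence. The acinar list was not called with the slide (camera adjusted p = 0.0879) or the replicate number (0.136) as a block. Its call was also lost with quantile normalization (0.178), median scaling (0.0640), normexp without smeared spots (0.137) and array weights (0.226). The same held for the stricter filter (0.0558) and the trended, robust eBayes (0.0512). The acinar call was also lost without control replicate 1 (-0.068) or 4 (0.15) and high-fat replicate 1 (-0.016) or 2 (0.12), and the mean was 0.37 without control replicate 3 and 0.30 without high-fat replicate 3.

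The 2 lists of immune cell markers were lower on average, with 0 members past an adjustment over either list alone. Lymphocyte genes fell by 1.11 on average over 18 members, 3 of them lower at an unadjusted p under 0.05 (camera adjusted p = 2.90e-06; adjusted p = 0.608 with an estimated correlation). The lymphotoxin gene Ltb differed by -1.96 ± 0.80 (-1.30 without high-fat replicate 3) and the T cell kinase Lck by -0.83 ± 0.26. High-fat replicates 1 and 3, at -3.35 and -3.50, carry this fall, while replicates 2 and 4 stood at -1.77 and -1.10 and the control samples between -1.61 and -0.94. The same 2 replicates were the lowest for the macrophage list, at -0.39 and -0.28. The SD of the high-fat arrays for lymphocyte genes was 1.18 against 0.28 for the control arrays (n = 4 each), and the slide means were -1.21 and -1.02. The size of the lymphocyte difference depends on the processing of these dim genes: it was -0.21 with normexp background correction, -0.47 with normexp without smeared spots, -0.26 in the deposited value table and -0.79 for genes well above background on all 8 arrays, and the list was called in each. Macrophage and dendritic cell genes fell by 0.39 on average over 24 members, 2 of them lower (camera adjusted p = 1.84e-05; adjusted p = 0.608 with an estimated correlation), with -0.60 on slide 1, -0.19 on slide 2, where the list was not called (adjusted p = 0.450), and -0.26 without high-fat replicate 1. Laptm5 differed by -0.80 ± 0.24 and the mannose receptor Mrc1, which stood near 0 with normexp background correction, by -1.13 ± 0.52 (-0.65 without control replicate 2, -1.85 on slide 1 and -0.40 on slide 2). Neural and Schwann cell genes fell by 0.46 on average over 8 members (camera adjusted p = 0.0116; adjusted p = 0.503 with an estimated correlation), with Gap43 at -0.83 ± 0.22. The neural list stood at -0.23 on slide 1, where it was not called (adjusted p = 0.357), and -0.68 on slide 2. The call was lost with normexp background correction (-0.19, adjusted p = 0.0855) and without high-fat replicate 1 (-0.40, 0.0929).

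The interferon response and immediate early lists were lower, but stood above 0 with normexp background correction. The interferon list fell by 0.13 on average (camera adjusted p = 0.0195, or 0.707 with an estimated correlation). Its mean was -0.42 on slide 1 and 0.17 on slide 2, where camera called the list higher (adjusted p = 0.0327). With 2 arrays per diet and the preset correlation, against an estimated 0.47 for this list, that call is weak evidence. The immunoproteasome gene Psmb9 stood at -0.64 ± 0.15. The interferon call was lost without control replicate 1 (0.085), high-fat replicate 1 (-0.048) or high-fat replicate 3 (-0.076), and the mean was -0.20 without control replicate 2, -0.24 without control replicate 3 and -0.23 without high-fat replicate 4. The immediate early and dissociation list fell by 0.15 on average (camera adjusted p = 0.0462; adjusted p = 0.608 with an estimated correlation). This call, close to the threshold, was lost on slide 1 (adjusted p = 0.0722) and slide 2 (0.327), with quantile normalization (0.0551), array weights (0.0995), the deposited value table (0.0860) and the mean of a gene's probes (0.0754). It was also lost without control replicate 1 (-0.12) or 3 (-0.035) and high-fat replicate 1 (-0.17), 2 (-0.12) or 3 (-0.11), and the mean was -0.23 without control replicate 4. Within the list Rgs2, a regulator of G protein signalling, stood at 1.56 ± 0.40 and Ier3 at -0.60 ± 0.13, the latter lower adjusted over the list alone but above 0 with normexp background correction. Endothelial (mean -0.087, camera adjusted p = 0.552), stellate (-0.028, 0.390), ductal (0.070, 0.378), adipocyte (-0.19, 0.153) and erythroid markers (0.23, 0.0548) did not pass as lists. The endothelial tight junction gene Cldn5 stood at -1.16 ± 0.43 and lipoprotein lipase (Lpl) at -0.84 ± 0.23. The glucose transporter Slc2a3 stood at -1.52 ± 0.30 and the cell cycle inhibitor Cdkn1a at 0.73 ± 0.20. The other lists did not pass either. Their mean and camera adjusted p were, for metabolism and secretion, the tricarboxylic acid cycle (0.067, 0.0770), glycolysis (0.0070, 0.110), autophagy and lysosome (0.044, 0.153) and exocytosis (-0.093, 0.266). For regulation and matrix they were circadian clock genes (-0.10, 0.0630), disallowed genes (-0.19, 0.0635), extracellular matrix (0.021, 0.165) and growth and adaptive response genes (-0.026, 0.793). For stress and inflammation they were inflammation (-0.20, 0.0630), hypoxia (-0.070, 0.394), apoptosis and p53 (0.031, 0.490), antioxidant genes (-0.040, 0.715) and heat shock (-0.040, 0.749). Some medians were opposite in sign to the mean. They were -0.091 for glycolysis, 0.019 for endothelial, 0.093 for stellate, 0.015 for antioxidant and 0.016 for heat shock genes. The dedifferentiation list had a mean of 0.34 and a median of -0.035.

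Over the 39 lists, camera with a preset correlation of 0.01 called 8 higher and 9 lower, against 2 higher and 18 lower with normexp background correction, and 0 with an estimated correlation, for which the smallest adjusted p was 0.184. At the preset correlation, splits of the arrays other than by diet called a median of 13 lists, so a call at that setting is weak evidence. Exact permutation of list means over the 70 assignments of the arrays gave its smallest possible p of 0.0286 to 3 lists, alpha cells, delta and PP cells and the unfolded protein response. Without a diet difference each list reaches this p with a probability of 0.0286, so over 39 lists some may reach it by chance. No other list had an exact p under 0.05. For the other called lists the exact p ran from 0.0857 (Reg family) to 0.657 (acinar cells), so this test did not support them even before adjustment. With 4 samples per diet the smallest p is too coarse to pass an adjustment over 39 lists unless many lists share it, so the count of 0 after adjustment says nothing.

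**Figure D2:**
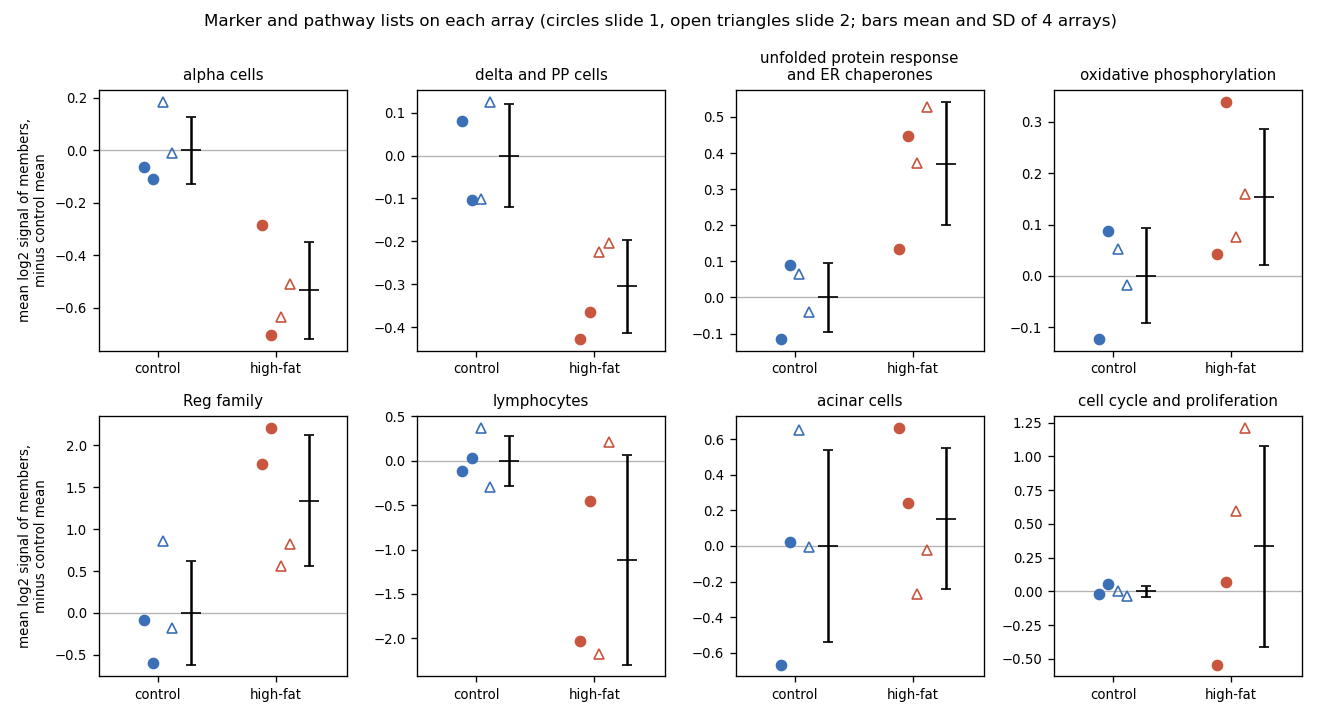
Mean log2 signal of the members of 8 lists on each array, minus the control mean (y axis, log2 units), for control and high-fat samples (x axis); circles are slide 1, open triangles slide 2, and bars the mean and SD of 4 arrays. The high-fat arrays lie below all control arrays for alpha cells (mean -0.53) and above them for the unfolded protein response (mean of the complete members 0.37), while acinar and cell cycle genes overlap between the diets.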

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

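The tests chosen only after the result was seen are those of a larger beta cell share, of fewer alpha cells, of acinar RNA, and of other splits for the count of genes past the threshold. Samples far from the rest of their group were sought in 200 groups of 4 samples, and 11 were found, where chance gives about 5%. Sample by sample they do not single out 1 array.

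Control replicate 3 stood apart for Scd1 at -2.43 and for Irx1 at 1.24 (log2 level relative to the 75th percentile), each well above the other 3 control samples, and for the median coefficient of variation of its spots at 5.61%. High-fat replicate 3 stood apart for Scd1 at -4.06, below its group, and for Cpt1a at 0.90, above it. Control replicate 2 stood low for Dennd2a at -1.55 and high for Mrc1 at -0.99, and control replicate 4 high for Upk3a at 0.25 and Ucp2 at 0.51. Sec11c was low in control replicate 1 at 2.69, and Gsto2 low in high-fat replicate 1 at -0.53, the sample without which Gsto2 passes the threshold.

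Alpha cell genes fell as a list (camera adjusted p = 0.184 with an estimated correlation), and a larger share of beta cells would lower every other cell type. Endothelial genes, however, stood at -0.087 and stellate genes at -0.028 on average, with medians of 0.019 and 0.093. The alpha cell score minus the mean of the endothelial and stellate scores differed between diets by -0.48 ± 0.17 (SE, exact permutation p = 0.114). That is over 2 SE, but the exact p misses 0.05, so it argues only weakly against a plain shift in share, and other lists went both ways. Delta and PP cells (-0.30), macrophages (-0.39), neural cells (-0.46) and lymphocytes (-1.11) were lower, as a larger share would predict (adjusted p = 0.184, 0.608, 0.503 and 0.608 with an estimated correlation), while acinar (0.15), ductal (0.070) and erythroid (0.23) lists lay above 0 and beta cell identity genes at -0.11. Fewer alpha cells would lower all their transcripts alike, but the 5 brighter members, Gcg, Ttr, Irx1, Etv1 and Slc38a5, fell less than the dimmer ones by 0.44 ± 0.15 (SE, exact permutation p = 0.0286, the smallest it can give), with means of -0.29 and -0.74. Irx1, at -1.10, goes with the dimmer genes, and Ttr is also made by beta cells, which may hide a loss of alpha cells for that gene. The contrast splits members by level, and a brightness trend may make up part of it. Random lists matched in level to the unfolded protein response and ribosomal lists had medians of 0.096 and 0.14, against 0.00093 over all genes. The dimmer part also holds Fap and Gria3, at levels of -3.70 and -3.06. The contrast thus cannot tell fewer alpha cells from lower expression within the cells. Lower expression of alpha cell regulators within the cells stays a hypothesis beside a change in the share of cells.

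Genes of the unfolded protein response, oxidative phosphorylation and ribosomal proteins were higher as lists, which the planned normexp correction takes to 0.017, -0.27 and -0.27, and normexp without the smeared spots to 0.33, 0.14 and 0.14 (adjusted p = 0.308, 0.608 and 0.681 with an estimated correlation and the main scaling). A trend with brightness would give any list of equally bright genes the same difference, and the median of the unfolded protein response list, 0.31, lay above all 10000 random lists matched on level (percentile 100, median of the random lists 0.096). For oxidative phosphorylation the percentile was 98.93 (0.15 against 0.11), and for ribosomal proteins it was 65.99 (0.15 against 0.14). A brightness trend may thus account for the ribosomal difference and for much of that of oxidative phosphorylation, whose mean was 0.050 after quantile normalization. The random lists drew genes independently. Members of the 3 lists move together (estimated correlation 0.26, 0.56 and 0.78), so the percentiles are too sharp, and 98.93 does not set brightness aside. With the acinar score of each array as a covariate the diet coefficient was 0.37 ± 0.11 (SE) for the unfolded protein response, unlike what acinar RNA alone predicts, and 0.10 ± 0.084 for ribosomal proteins, within 2 SE of 0. For the ribosomal list acinar RNA and diet cannot be told apart with 8 arrays, and array position stays open for all 3 lists because it follows diet on both slides.

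Reg family genes were higher, led by Reg3a and Reg2 (adjusted p = 0.503 with an estimated correlation). Acinar RNA carried into the high-fat samples would raise both groups alike, but the Reg family score minus the acinar score differed by 1.19 ± 0.37 (SE, exact permutation p = 0.0286, the smallest it can give). Both list differences had been seen when this contrast was chosen. The Reg family stood at 2.33 on slide 1 and 0.35 on slide 2, and the acinar list at 0.78 and -0.47. On slide 2 the gap thus came more from lower acinar genes than from higher Reg genes. Acinar transcripts are abundant in all samples, with Cela3b at 8.52 ± 0.55 in control and 8.82 ± 0.45 in high-fat samples (SD, n = 4). A response of Reg genes in islet or acinar cells may explain the difference, as may array position, and the data hold no test between them.

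Chance is not excluded for the count of genes at an unadjusted p under 0.05 or for the count of lists. For the genes that limma called, the count for diet was 0 (1171 at an unadjusted p under 0.05), which all 35 of 35 splits of the 8 arrays must reach, so that comparison says nothing; the highest other split gave 785, which is the split by slide. For genes at an unadjusted p under 0.05, 12 of 35 splits gave as many as the 1171 for diet, up to 3818 for the slides. For lists, 4 of 35 splits gave at least 17, the split by diet included. Splits other than diet gave a median of 13 lists. Camera at the preset correlation thus called many lists for a typical grouping of these arrays, and its adjusted p-values overstate the evidence. The highest other split gave 25, while the split by slide gave 4. The slides are thus the stronger structure of the samples for single genes, and with the slide as a block the diet gave 0 genes (1466 at an unadjusted p under 0.05) and 17 lists. In the simulated data the same fit found 14 of 50 genes changed 1.5-fold, 28 of 50 changed 2-fold and 42 of 50 changed 4-fold. It made 8 false calls in all. The fit can thus make calls with 4 arrays per diet where noise is independent, but it misses most changes of 1.5-fold. The real arrays have a slide effect and correlated genes, so the counts of calls and false calls need not hold for them.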

How the results depend on the processing

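The normexp correction without smeared spots was chosen only after its planned form had been seen, and Gsto2 and Gm2115 are named here after their values were seen; the other alternatives were set before the data were examined. Over the alternatives, 51 of 1713 values of the 78 named genes and 14 of 374 values of the 17 called lists turned sign. In 53 list values the call was lost, 46 with the same sign and 7 with the sign turned, and 7 others were called the opposite way.

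The planned normexp correction with an offset of 50 turned 22 genes and 6 lists, more than any other setting, because a background smear over 7 spots of high-fat replicate 2 moves the fit of that array. The values were 0.39 for Mbl2, 0.44 for Actn3, 0.00088 for Fam163a, 0.42 for Insyn2a, 0.53 for Kcnh8, 0.10 for Eef1a2, -0.39 for Ins1, -0.37 for Ins2, -0.38 for Iapp and -0.36 for Ucn3. They were 0.40 for Scd1, -0.075 for Hsp90b1, -0.018 for Ndufa1, -0.11 for Uqcrq, -0.14 for Acadvl, -0.073 for G6pc2, 0.42 for Ghsr, 0.49 for Kcnn2, -0.17 for Atp2a3, 0.15 for Ier3, 0.00097 for Mrc1 and -0.14 for Cela3b. The lists stood at -0.27 for oxidative phosphorylation, 0.00040 for interferon response, 0.018 for immediate early genes, -0.27 for ribosomal proteins, -0.28 for the proteasome and -0.26 for acinar cells. Limma called 0 genes (147 at an unadjusted p under 0.05) and camera 20 lists, 2 higher and 18 lower. Of these 12 are among the 17, but 4 of the 12, oxidative phosphorylation, ribosomal proteins, proteasome and acinar cells, are called the opposite way. The unfolded protein response list stood at 0.017 and was not called (adjusted p = 0.236). Without the smeared spots no named gene or called list turned sign, with 0 genes past the threshold (728 at an unadjusted p under 0.05) and 20 lists, 15 of them among the 17.

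Median scaling gave 0.039 for Ppy. Quantile normalization gave -0.077 for Ins1, -0.012 for Ins2, -0.017 for Iapp and -0.088 for Ucn3 and ended 5 list calls, among them oxidative phosphorylation (adjusted p = 0.0534) and ribosomal proteins (0.235). Of the 17 list means, 13 were over 1.5 times smaller in the deposited value table and 7 with the planned normexp. In the value table the dimmest probes stood at 250 to 253 on the linear scale, which may compress log2 differences. As many as 5 list means shrank so with normexp without smeared spots and 4 with quantile normalization. Median scaling made 4 smaller and 2 larger by as much, and the planned normexp made 1 larger. The value table called 1 gene, Gfra3, with Ucn3 at -0.061 and the proteasome list at -0.0024, and the trended, robust eBayes called 1 gene, again Gfra3. Array weights gave -0.061 for Ins1 and -0.015 for Ucn3.

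Slide 1 alone gave 0.10 for Gcg, -0.013 for Ucn3, -0.46 for Mki67 and -0.26 for the cell cycle list. Slide 2 alone gave -0.32 for Ins1, -0.34 for Ins2, -0.32 for Iapp, 0.34 for Ppy, -0.32 for Cela3b, 0.17 for the interferon list, -0.046 for the ribosomal list and -0.47 for the acinar list. With the slide as a block limma called 0 genes (1466 at an unadjusted p under 0.05) and camera 17 lists, 16 of them the same. The replicate number as a block gave 0 genes (1851) and 18 lists, 16 of them the same, though the numbers are not known to pair samples. Deviations from the diet means correlated at 0.21, 0.40, -0.0030 and 0.30 between samples of equal number (1 to 4). Between unequal numbers the range was -0.29 to 0.16. Samples of equal number lay on the same slide at neighbouring positions, so slide or position may raise their values. A pairing is thus neither shown nor excluded, and the splits and permutations took no account of one.

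Leaving out 1 sample at a time gave 0 to 2 genes past the threshold. The 2 were Gsto2 at 1.48 and Gm2115 at 2.36 without high-fat replicate 1, where 2067 genes had an unadjusted p under 0.05, against 1880 without control replicate 3 and 1171 with all samples. The lists called ranged from 15 to 23. The similarity of arrays ranged from -0.00028 to 0.00268 and turned sign without control replicate 1, control replicate 2 or high-fat replicate 4. Ranges that cross 0 were -0.10 to 0.14 for Ins1, -0.064 to 0.14 for Ins2, -0.12 to 0.15 for Iapp, -0.20 to 0.13 for Ppy and -0.090 to 0.12 for Ucn3. The interferon list ranged from -0.24 to 0.085 and the acinar list from -0.068 to 0.37.

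The count of 17 lists depends on the test. Camera with an estimated correlation called 0 lists (3 at an unadjusted p under 0.05) and fry 2. Exact permutation of list means also gave 0, but its smallest p, 0.0286, which 3 lists had, is too coarse for 39 lists, so that 0 says nothing. Without adjustment, the other called lists had an exact p of 0.0857 or more.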

Other observations

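The tests of the imprinted genes were chosen only after Mest and Nnat had been seen to be lower, though the bound for the group test was written before that test was run. Mest and Nnat are expressed from 1 parental copy, and both were lower after the high-fat diet, with log2 differences of -0.84 ± 0.13 and -1.18 ± 0.29 (SE). Other imprinted genes went the same way, with -0.86 ± 0.19 for Dlk1, -0.52 ± 0.11 for Sgce and -0.57 ± 0.14 for Grb10, and these 3 passed adjusted over the list alone without Mest and Nnat (adjusted p = 0.0329, 0.0329 and 0.0383), while none passed over all genes.

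A list of imprinted genes without Mest and Nnat had 38 measured members, 26 below 0 and 12 above, with a mean log2 difference of -0.16. Of these, 7 were lower and 2 higher at an unadjusted p under 0.05. Camera gave p = 0.00156 at the preset correlation and 0.0902 at an estimated correlation, and the exact permutation p of the list was 0.114. The bound set beforehand for the estimated correlation was 0.05, and it was not met, so a lower level of imprinted genes as a group is not shown. That bound would also have counted against the idea itself, a reading dropped after the value was seen because a p above a threshold rules nothing out. A shared lowering of imprinted genes may be a hypothesis for other data, and it was 1 idea picked among the 39 lists and the many genes looked at here.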
